A study of Homo sapiens with 18 samples.

How the data were processed

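Total RNA of HCT116 cells was sequenced in 18 libraries, as 50 bp paired-end reads per the labels. The cells were knock-ins of wild-type IκBα (WT), of the N108 mutant or of the M3 mutant, each untreated or treated with human TNFα at 0.1 µg/mL for 40 min, with 3 replicates per group. Groups and replicate numbers were taken from the titles of the samples, and every column of values was matched to a sample by its name.

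The authors deposited a table of raw read counts per gene for all libraries, with Ensembl identifiers. Per the submitters' processing notes, the tools named were Trim Galore 0.6.6, STAR 2.7.8, featureCounts of Subread 2.0.1 and DESeq2 1.38.3, with the hg38 build. The annotation release and the strand setting of the counting are not given in the sources used here. Whether reads of a gene were told apart from those of one that overlaps it on the other strand is therefore not known. The authors also deposited a normalized table whose values lie on a log2 scale. It held the genes with at least 10 counts in total, the highest total left out being 9, and it was checked but not used for any test because a test on counts was possible. Gene symbols were matched for 99.8% of the genes from a name table. Positions and transcript GC content came from GENCODE 29 on GRCh38, which covered 97.4% of the genes tested. Coordinates are those of GENCODE 29, since the annotation used for counting is not given.

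The raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10, which left 19038 genes holding 99.97% of the counts. Libraries were scaled with TMM factors. One quasi-likelihood model (robust) was fitted with a mean for each of the 6 groups over all 18 libraries, leaving 12 residual degrees of freedom, so that the groups shared the estimate of spread. From it came 10 comparisons: TNF against untreated in each genotype, each mutant against WT untreated and with TNF, N108 against M3 untreated, and the interaction of TNF with each mutant. All p-values per gene are from edgeR's quasi-likelihood test, two-sided, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors were derived from the same test as the absolute log2 fold change over the square root of F. Levels are CPM, computed from TMM-scaled library totals, as mean ± SD over 3 libraries. Where a group held 0 counts, a bound on the fold was computed from a floor of 3 counts over the group. Intervals and floors of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

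Gene lists, 30 in number with 858 genes, were fixed from general knowledge before the data were examined, as were the tests, most of the other settings tried and the rule for naming genes. They covered NF-κB and immediate early responses, intestinal stem cell and differentiation programmes, developmental and stress pathways, housekeeping groups and markers of other cell types. Only members among the genes tested were counted. The adult stem cell list thereby lacked LGR5, ASCL2, OLFM4, SMOC2, PTPRO and HOPX. The enterocyte list kept 8 members, without VIL1, FABP1, SI and CDX1 among others. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation. A count adjusted over the list alone applied Benjamini-Hochberg to the members' p-values only. Some genes stood in several lists, such as NFKBIA (early NF-κB targets and components) and AXIN2 (adult stem cell and Wnt/β-catenin), so the results of such lists are not independent. Named genes were the 6 highest and 6 lowest (3 for the other comparisons) by log2 fold change in each of TNF in WT, N108 against WT and M3 against WT, untreated. They had to pass the threshold with at least 1 CPM in the higher group, groups that did not overlap, and a symbol that was not a clone identifier. Added to them were the 3 members with the smallest p of each list discussed, NFKBIA and the NF-κB subunit genes in every comparison, and the values of genes already named elsewhere.

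Library totals of 49021907 to 76947190 counts set the precision. In counts simulated from these libraries, with 100 genes changed at each size, 100 genes with an absolute log2 fold change of 1 and 88 with 0.5 were recovered for TNF in WT (3.59% of calls false). For N108 against WT untreated 97 and 86 were recovered (5.67% false), and for the interaction with N108 94 and 68 (6.36% false). These rates came from a single simulated set, with independent genes and no GC trend that differed between libraries. They therefore cannot show how lenient the adjusted p-values were in the real data. A simulated shift of 0.3 in a list of 25 genes was called, and 0 of 29 random lists were.

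Settings chosen in advance were DESeq2 1.42.0, DESeq2 size factors in edgeR, a stricter low-count filter (1 CPM in 3 libraries), no filter, a replicate block, a fit of only the groups compared, a 2-fold threshold, an estimated correlation for the lists and leaving out each library in turn. After the data were seen, a GC correction was added, in which each library's smooth trend of log2 CPM on transcript GC content (a spline with 5 degrees of freedom) was removed through offsets, together with leaving out libraries in the list tests. Other splits of the samples, simulated unchanged groups against the shared WT libraries and levels of genes near NFKBIA were tested as well. Sequence-level checks of the edited codons were not possible from counts per gene and were not analysed here. A few single-gene results are not reported here.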

Results

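RNA was measured in HCT116 cells, a human colorectal carcinoma line with an epithelial origin, that carried a knock-in of IκBα, the inhibitor that holds NF-κB dimers in the cytoplasm until a signal such as tumour necrosis factor (TNF) triggers its breakdown. The labels tell apart 3 lines: a knock-in of the wild-type protein (WT), a knock-in named for residue 108 (N108) and a knock-in with alanine at residues 84, 85 and 86 (M3). Each line was sequenced untreated and after 40 min with human TNFα at 0.1 µg/mL, giving 6 groups of 3 libraries and 18 libraries in all. Library totals lay between 49021907 and 76947190 counts. The title of the series asks about a role of IκBα in intestinal stemness that is separate from NF-κB, using mutants that part its functions. Genotype separated the libraries along the first principal component, which held 49.9% of the variance, with WT between 49.2 and 57.7, N108 between -11.6 and -6.73 and M3 between -44.3 and -42.4. Treatment separated them along the third component (6.91% of the variance). No pair of replicates agreed within sampling noise, with chi-square values per degree of freedom from 3.42 to 23.5. Because the labels do not say whether replicates were separate cultures, p-values measure the spread between these libraries, which may be technical. They also name 1 line per genotype, so a mutation cannot be separated here from the clone that carries it.

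NFKBIA, which encodes IκBα (ENSG00000100906, chromosome 14, 35401511 to 35404749, minus strand, GRCh38), was read in every group first. Untreated cells held 91.6 ± 4.6 CPM (counts scaled by library total) in WT, 30.3 ± 1.8 in N108 and 77.9 ± 1.2 in M3 (mean ± SD, n = 3 each). With TNF the same transcript stood at 758 ± 20 CPM in WT, 276 ± 19 in N108 and 966 ± 21 in M3. N108 was lower than WT both untreated (log2 fold change -1.60, SE 0.053, adjusted p = 2.1e-19) and with TNF (-1.46, SE 0.05, adjusted p = 5.1e-19). M3 was slightly lower than WT untreated (-0.23, SE 0.051, adjusted p = 0.00036) and higher than WT with TNF (0.35, SE 0.049, adjusted p = 9.1e-07). Counts per gene carry no information on the altered residues themselves. Among the NF-κB subunit genes, NFKB1, which encodes the p105 precursor of p50, was lower than WT in untreated N108 (-0.31, adjusted p = 1.2e-06) and M3 (-0.46, adjusted p = 7.1e-10). RELA, which encodes p65, was also lower in both (-0.22 and -0.18, adjusted p = 0.00039 and 0.0021). NFKB2 and RELB, the subunits of the alternative pathway, differed from WT by at most 0.12 in either line and did not pass the test.

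**Figure D1:**
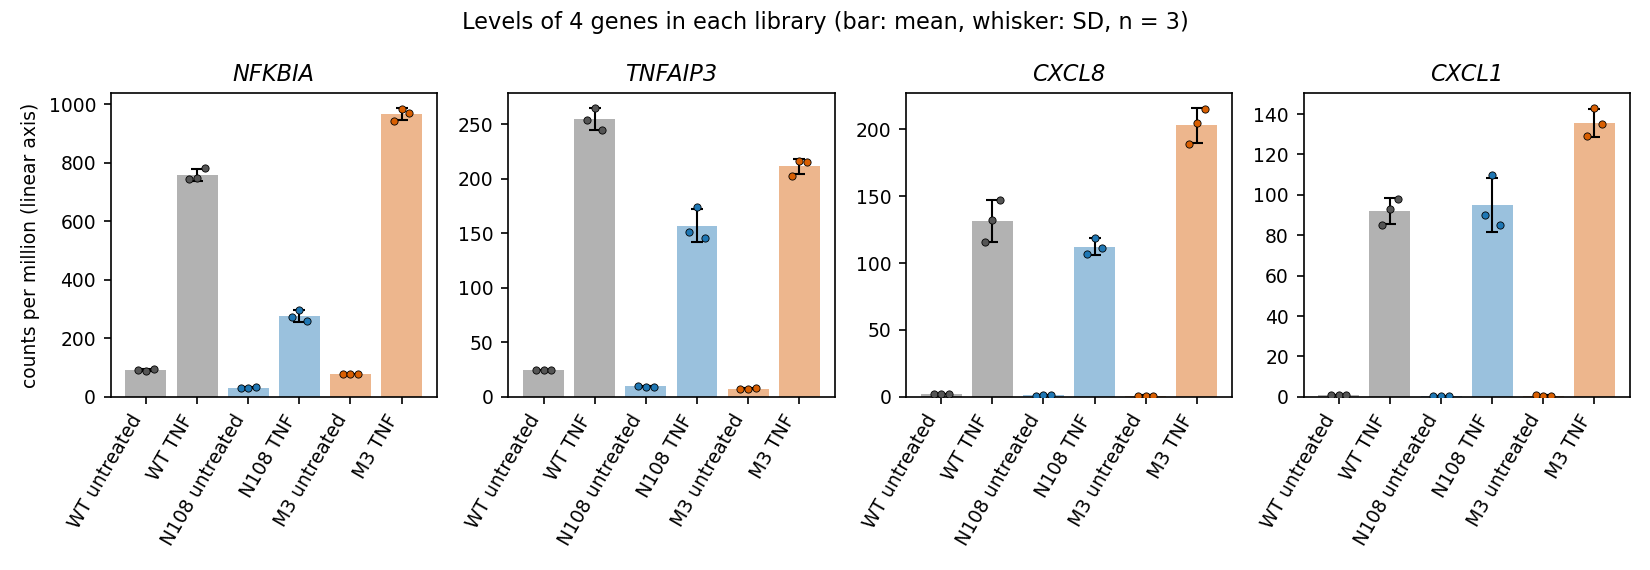
CPM on a linear axis (vertical) of NFKBIA, TNFAIP3, CXCL8 and CXCL1 in the 6 groups (horizontal); bars are means, whiskers SDs and points the 3 libraries of each group. NFKBIA was lowest in N108 in both conditions (30.3 CPM untreated, 276 CPM with TNF), and CXCL8 reached 203 CPM in M3 with TNF against 132 CPM in WT.

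TNF raised chemokine and NF-κB feedback transcripts of WT cells within 40 min. CXCL8, a neutrophil chemoattractant (chromosome 4, 73740506 to 73743716), rose from 1.92 ± 0.097 to 132 ± 15 CPM (log2 fold change 6.11, SE 0.088, adjusted p = 4.2e-27, n = 3 per group). CXCL1, of the same chemokine family (chromosome 4, 73869393 to 73871242), rose from 0.926 to 92 ± 6.4 CPM (6.64, SE 0.11, adjusted p = 1.5e-22), and CXCL2 and CXCL3 rose by 6.52 and 6.09. CCL20, which attracts cells through CCR6 (chromosome 2, 227805739 to 227817564), rose from 0.0231 to 4.24 ± 0.83 CPM. The TNF transcript itself went from 0.00667 CPM, near the limit of detection, to 1.52 ± 0.13 CPM. NFKBIA rose by 3.05 (SE 0.054, adjusted p = 2.8e-25), and TNFAIP3, which encodes the deubiquitinating feedback inhibitor A20 (chromosome 6, 137867188 to 137883312), rose by 3.36 (SE 0.061), from 24.8 ± 0.19 to 255 ± 10 CPM.

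Across the lists of genes fixed in advance, 29 of 35 measured early NF-κB targets rose in WT and none fell (32 adjusted over the list alone; camera's competitive test, adjusted p = 8.4e-06 with an estimated correlation). Immediate early genes, the transcripts that respond to many stimuli within minutes, rose for 25 of 35 members and fell for 1 (28 and 1 adjusted over the list alone; adjusted p = 0.0081 with an estimated correlation). Their rises included those of JUN (2.81), JUNB (2.11) and ZFP36 (1.87), the last encoding an RNA-binding protein that destabilises cytokine mRNA. NF-κB and IκB components rose for 8 of 27 members (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.0081 with an estimated correlation), among them NFKBIE (0.92), RELB (0.44) and NFKB2 (0.41). RELA (0.07) and NFKB1 (0.09) did not pass. Targets of p53 rose for 7 of 29 (9 adjusted over the list alone; adjusted p = 0.023 with an estimated correlation), including BTG2 (1.35), the proapoptotic BBC3 (0.68) and GDF15 (0.59). YAP/TAZ targets rose for 5 of 22 (5 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation), including NUAK2 (3.03) and CCN1 (0.70).

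Another 6 lists passed camera with its preset correlation only. Heat shock genes rose for 3 of 20 (8 adjusted over the list alone; adjusted p = 0.08 with an estimated correlation), cholesterol synthesis genes for 4 of 25 (6; adjusted p = 0.2) and genes of the unfolded protein and ATF4 response for 4 of 27 (4; adjusted p = 0.26). The fetal-like regenerative list rose for 4 of 27 members (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), AREG (0.46), an EGF receptor ligand, and PLAUR (0.58) among them. Epithelial junction genes rose for 1 of 24, CLDN4 at 0.37 (2 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation). None of 15 mitochondrially encoded transcripts passed on its own (adjusted p = 0.67 with an estimated correlation). The adult intestinal stem cell list had 0 of 18 members past the edgeR test in WT, with 4 higher and 2 lower at an unadjusted p under 0.05. Transcripts that fell the most included ATG9B (-1.10), an autophagy gene, the cytokine receptor gene IL11RA (-0.95) and CAPN3 (-0.92). ASMTL-AS1 (-1.37), CTNS-AS1 (-1.15) and LINC02990 (-1.14) fell too, but antisense and overlapping genes are uncertain since the strand setting of the counting is not given in the sources used here.

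Over all 19038 genes tested, edgeR's quasi-likelihood test called 387 higher and 600 lower with TNF in WT, 99 of them by at least 2-fold. Transcript GC content differed between the calls, with a median of 46.9% for the higher and 58.2% for the lower against 48.6% for all genes. With each library's GC trend removed, 431 genes were higher and 699 lower, and 850 of the 987 were still called. The count of 987 rested in part on single libraries: it was 432 without WT TNF replicate 3 and 562 without WT untreated replicate 2.

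In N108 cells TNF raised chemokine transcripts too. CXCL8 rose from 1.02 to 112 ± 6 CPM (log2 fold change 6.78, SE 0.095), CXCL1 from 0.522 to 95.1 ± 14 CPM (7.52, SE 0.12), and CCL20 went from 0.00869 to 3.34 ± 0.74 CPM. TNFAIP3 rose from 9.51 to 157 ± 15 CPM (4.04), and NFKBIA by 3.19 (SE 0.055). Early NF-κB targets rose for 26 of 35 members and none fell (27 adjusted over the list alone; adjusted p = 4.4e-06 with an estimated correlation). Immediate early genes rose for 22 of 35 (26; adjusted p = 0.0033 with an estimated correlation), with JUN at 3.23 and JUNB at 1.96. NF-κB and IκB components rose for 8 of 27 (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.0015 with an estimated correlation), NFKB2 by 0.56 and RELB by 0.36. RELB's call ended without N108 untreated replicate 2 (adjusted p = 0.37). RELA (0.16) and NFKB1 (0.06) did not pass.

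The lists for YAP/TAZ targets, p53 targets, the unfolded protein response and the Notch pathway passed camera in N108 only with its preset correlation. They rose for 5 of 22, 5 of 29, 3 of 27 and 1 of 16 members (5, 7, 8 and 5 adjusted over the list alone, where 1 p53 target was also lower), and their adjusted p with an estimated correlation was 0.14, 0.14, 0.23 and 0.23. NUAK2 (2.79), BTG2 (1.15) and PLK3 (0.75), a stress-induced kinase gene, were among those that rose. KRT222 (-0.73, SE 0.18, adjusted p = 0.04), GAS1 (-0.58) and RBM43 (-0.49) fell most, and the adjusted p of KRT222 and GAS1 rose above 0.05 without N108 untreated replicate 2 (0.23 and 0.14). edgeR called 209 genes higher and 19 lower, and 50 by at least 2-fold. This count was 1333 without N108 TNF replicate 3, 143 without N108 untreated replicate 2 and 151 without N108 TNF replicate 2. Across genes, the TNF fold change in N108 followed transcript GC content (Spearman 0.72, genes not being independent replicates), with decile medians from -0.125 at a GC content of 37% to 0.121 at 64.3%. Single libraries differed in this trend, N108 TNF replicate 2 at 0.75 and N108 TNF replicate 3 at -0.47. With the trend removed, 171 of the 228 genes were still called.

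**Figure D2:**
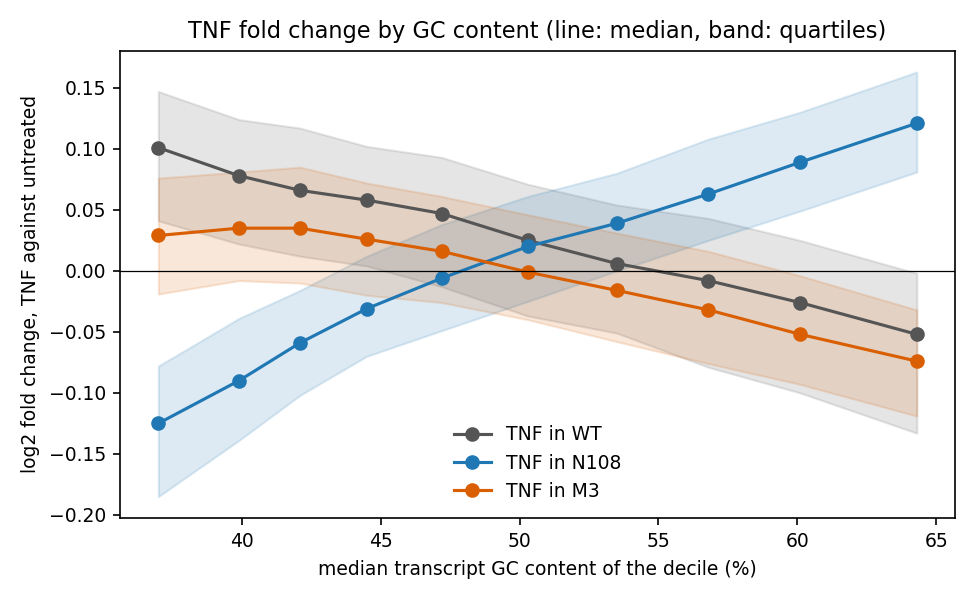
Log2 fold change with TNF (vertical) against the median transcript GC content in percent (horizontal) of 10 equal groups of genes, for WT, N108 and M3; lines are medians and bands quartiles over genes. The N108 medians climb from -0.125 to 0.121, while those of WT go from 0.101 to -0.052 and those of M3 from 0.029 to -0.074.

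M3 cells gave the highest levels of several TNF-induced transcripts, but not of all. The TNF transcript reached 0.831 ± 0.17 CPM in M3 against 1.52 ± 0.13 CPM in WT, and TNFAIP3 was also highest in WT (255 ± 10 CPM). CXCL8 rose from 0.946 to 203 ± 13 CPM (log2 fold change 7.74, SE 0.098), CXCL1 from 0.619 to 135 ± 7.1 CPM (7.77) and CCL20 by 8.08, to 8.25 CPM. TNFAIP3 rose from 7.58 ± 0.56 to 211 ± 6.7 CPM (4.80), and NFKBIA by 3.63 (SE 0.055). Early NF-κB targets rose for 28 of 35 members and none fell (30 higher and 1 lower adjusted over the list alone; adjusted p = 7.8e-07 with an estimated correlation). Immediate early genes rose for 22 of 35 and fell for 1 (26 and 3; adjusted p = 0.0015 with an estimated correlation), JUN by 3.55 and ATF3 by 1.86. NF-κB and IκB components rose for 8 of 27 (9; adjusted p = 0.00077 with an estimated correlation), with NFKB2 at 0.47 and RELB at 0.40, the latter past the threshold but not without M3 TNF replicate 3 (adjusted p = 0.15). Targets of p53 rose for 7 of 29 (7; adjusted p = 0.0015) and YAP/TAZ targets for 5 of 22 (5; adjusted p = 0.045), both with an estimated correlation.

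HOX genes, which specify position along the body axis, fell for 4 of 32 members in M3 with TNF (7 adjusted over the list alone; adjusted p = 0.0015 with an estimated correlation), HOXB5 (-0.30), HOXA10 (-0.26) and HOXB6 (-0.25) among them. These 3 calls ended without M3 TNF replicate 1 (adjusted p = 0.12, 0.079 and 0.055). The fall was not particular to M3, since HOXB5 (41.3 to 32.7 CPM) and HOXB6 (90.7 to 73.8 CPM) fell with TNF in WT too. Hypoxia and glycolysis genes fell for 4 of 30 members (16 adjusted over the list alone), and the list's adjusted p was 4.5e-15 with the preset correlation and 0.18 with an estimated correlation. ADM, which encodes the vasodilator adrenomedullin, fell from 47.9 to 30.3 CPM (-0.66, SE 0.074, adjusted p = 9.1e-07). EGLN3, a HIF prolyl hydroxylase gene, fell from 12 to 7.8 CPM (-0.62, adjusted p = 0.00025), and ANGPTL4 and MIR210HG fell by 0.76 and 0.74 on the log2 scale. ANGPTL4 no longer passed without M3 untreated replicate 3 (adjusted p = 0.14). Means of ADM, EGLN3 and ANGPTL4 were lower with TNF in WT and N108 too, such as ADM (25 to 21.1 and 31.1 to 25.9 CPM). MIR210HG was lower in WT (5.36 to 4.2 CPM) but not in N108 (9.41 to 9.7 CPM). At an unadjusted p under 0.05, 22 of the 30 hypoxia genes were lower in M3, against 1 in WT and 2 in N108. As many were higher in WT and N108 (1 and 2), and 0 in M3. Wnt/β-catenin targets went both ways, 2 higher and 3 lower of 18 (2 and 5 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), with the feedback genes AXIN2 at -0.39 and SP5 at -0.46 against MYC at 0.34. AXIN2 and SP5 also had lower means, and MYC a higher mean, with TNF in WT and N108. Heat shock, unfolded protein response and ribosomal protein lists passed with the preset correlation alone, with 0 of 20, 2 higher and 1 lower of 27, and 0 of 74 members past the edgeR test (3 higher and 4 higher with 1 lower adjusted over the list alone for the first pair; adjusted p = 0.23, 0.41 and 0.73 with an estimated correlation). In all, 209 genes were higher and 53 lower, 64 by at least 2-fold. The TNF fold change in M3 also followed transcript GC content (Spearman -0.42). Median GC content was 51% for the higher and 58% for the lower calls, against 48.6% for all genes. M3 untreated replicate 3 differed in this trend (0.70) from replicates 1 and 2 (-0.25 and -0.20). With each library's GC trend removed, 245 genes were higher and 87 lower, and 248 of the 262 were still called.

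TNF raised 132 genes in all 3 genotypes, with median log2 fold changes of 0.70 in WT, 0.64 in N108 and 0.72 in M3, and lowered 2. Of the genes that rose, WT shared 149 with N108 and 170 with M3, where independent lists would share 4.25 in both cases, and the mutants shared 144 (2.29 for independent lists). Of the genes that fell, 2, 12 and 7 were shared in the same order (0.599, 1.67 and 0.0529 for independent lists).

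Whether the response to TNF differed between genotypes was tested as an interaction. In M3, 9 named genes of the TNF response rose by more than in WT. CXCL8 rose by a further 1.63 on the log2 scale (SE 0.15, adjusted p = 3.7e-07), TNFAIP3 by 1.44 (SE 0.087, adjusted p = 3e-11) and NFKBIZ, an atypical IκB that acts in the nucleus (chromosome 3, 101827991 to 101861022), by 1.33 (SE 0.1, adjusted p = 8.7e-09). JUN (0.74, adjusted p = 0.00032), NFKBIA (0.58, adjusted p = 3.5e-05), ATF3 (0.57, adjusted p = 0.0028), CXCL1 (1.13, adjusted p = 0.03), NUAK2 (0.63, adjusted p = 0.043) and ZFP36 (0.35, adjusted p = 0.043) passed as well. The last 3 ended as calls without WT untreated replicate 2 (adjusted p = 0.089, 0.1 and 0.12). Both the untreated and the treated level entered this: TNFAIP3 stood at 7.58 CPM untreated in M3 against 24.8 in WT and was also lower with TNF (211 against 255 CPM), whereas CXCL8 was lower untreated and higher with TNF. HAL, a histidine-degrading enzyme gene, fell from 0.797 to 0.334 CPM in WT and stood at 0.931 and 1.05 CPM in M3 (interaction 1.42, adjusted p = 0.03). Responses were smaller in M3 for ADRB1 (-0.91), DEPP1 (-0.75, adjusted p = 1e-04) and TSC22D3 (-0.51), the last encoding a glucocorticoid-induced leucine zipper protein. The calls of HAL, ADRB1 and TSC22D3 ended without WT untreated replicate 1 (adjusted p = 0.068, 0.07 and 0.051). DEPP1, a FOXO target, went from 15 to 31.4 CPM in WT and from 10 to 12.6 CPM in M3.

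Early NF-κB targets had 8 of 35 members with a larger rise in M3 and none with a smaller one (11 adjusted over the list alone; camera adjusted p = 7.4e-07, and adjusted p = 0.17 with an estimated correlation). Hypoxia genes had 0 of 30 past the edgeR test, with 0 higher and 14 lower at an unadjusted p under 0.05 (4 lower adjusted over the list alone; adjusted p = 0.34 with an estimated correlation). Epithelial junction genes had 0 of 24 past it and 7 lower at an unadjusted p under 0.05, with a median of -0.12 (adjusted p = 0.041 with an estimated correlation). The other 7 lists that passed camera did not hold with an estimated correlation (adjusted p from 0.17 to 0.6). edgeR called 60 interactions, 54 higher and 6 lower in M3. The count was 14 without WT untreated replicate 1, 16 without WT untreated replicate 2, and 125 without WT TNF replicate 1. With each library's GC trend removed it was 230, of which 183 were higher, and 59 of the 60 remained.

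**Figure D3:**
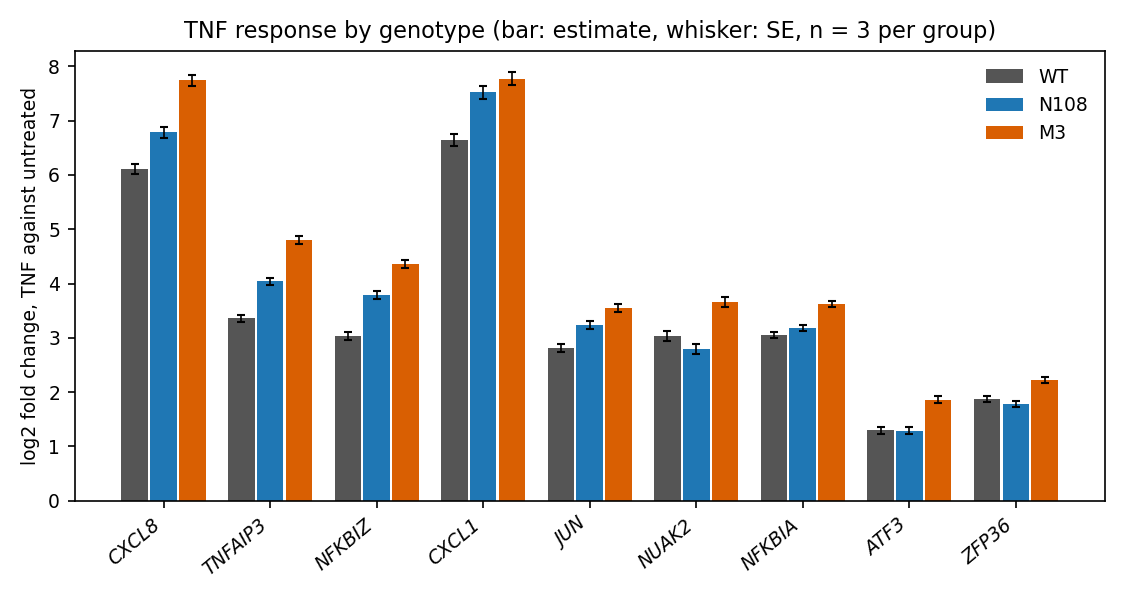
Log2 fold change with TNF against untreated (vertical) of 9 genes whose rise was larger in M3 than in WT (horizontal), for WT, N108 and M3; bars are edgeR estimates and whiskers their SEs, from 3 libraries per group. CXCL8 rose by 6.11, 6.78 and 7.74 and TNFAIP3 by 3.36, 4.04 and 4.80 in WT, N108 and M3.

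The same interaction was tested for N108, against the same WT libraries. On the log2 scale, the rise of TNFAIP3 was larger than in WT by 0.68 (SE 0.085, adjusted p = 0.00026) and that of NFKBIZ by 0.76 (SE 0.1, adjusted p = 0.00054). Their untreated levels entered this: TNFAIP3 stood at 9.51 CPM untreated in N108 against 24.8 in WT, and at 157 against 255 CPM with TNF. NFKBIZ stood at 3.93 against 6.58 CPM untreated and at 54.5 against 53.8 CPM with TNF. BIRC3, which encodes the inhibitor of apoptosis cIAP2, rose by less (-0.67, adjusted p = 0.0033). NFKBIA did not differ in response (0.14, SE 0.072, adjusted p = 0.26). CXCL8 (0.67, adjusted p = 0.016), CXCL1 (0.87, adjusted p = 0.041) and JUN (0.42, adjusted p = 0.026) passed too, but lost their calls with the GC trend of each library removed (0.95, 0.93 and 0.31, adjusted p = 0.1, 0.25 and 0.064). TNFAIP3 and NFKBIZ kept theirs (0.68 and 0.80, adjusted p = 8.7e-05 and 1e-04). BIRC3 did not (-0.42, adjusted p = 0.13). EGR3, an immediate early transcription factor gene, rose by less in N108 (-0.76, adjusted p = 0.004), and LINC02990 (1.27), ADAM8 (1.23) and SYT8 (1.20) had the highest interaction estimates of the genes named. No list passed camera in this comparison (5 at an unadjusted p under 0.05), though 5 did with the GC trend removed and 5 without WT TNF replicate 2. Early NF-κB targets had 4 higher and 2 lower of 35 (4 and 6 adjusted over the list alone). edgeR called 498 interactions, 387 higher and 111 lower in N108, and 147 after the GC trend was removed. Median GC content was 61% for the higher and 40.5% for the lower calls. Single libraries moved the count to 183 (without WT TNF replicate 3) or 2430 (without N108 TNF replicate 3).

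Untreated N108 and WT cells were compared to see what the N108 line changed without a signal. ACSL5, an acyl-CoA synthetase of intestinal fatty acid metabolism (chromosome 10, 112374018 to 112428380), stood at 427 ± 3.4 CPM in N108 against 39.9 ± 2 CPM in WT (log2 fold change 3.42, SE 0.047, adjusted p = 2.3e-28, n = 3 per group). ANXA10, a calcium-binding annexin gene (chromosome 4, 168092515 to 168187690), was at 29.7 ± 1.5 against 2.57 CPM (3.52, SE 0.086), and KCNQ3 and HEPH, the iron-oxidising hephaestin gene, were higher by 3.69 and 3.16. LINC00960 was at 2.33 CPM in N108 and 0.0161 CPM in WT. On the other side, PLEKHS1 (chromosome 10, 113751454 to 113783429) was at 0.232 CPM in N108 against 46.4 ± 0.65 CPM in WT (-7.63, SE 0.1, adjusted p = 2.3e-28). ANKRD1, a YAP/TAZ target, was at 0.0109 against 2.1 CPM, BPIFB1 at 0.12 against 14.4 CPM and KRTAP3-1 at 0.174 against 15.6 CPM. PSG4 (-6.82) was also lower but is uncertain because it shares sequence with close paralogs.

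Interferon-stimulated genes were lower in N108 for 26 of 28 members and higher for 1 (26 and 2 adjusted over the list alone; adjusted p = 3e-05 with an estimated correlation). BST2, which tethers budding virions (chromosome 19, 17402939 to 17405648), fell from 15.3 CPM in WT to 2.74 CPM in N108 (-2.48, SE 0.089), with IFIT1 at -1.83 and IFI35 at -1.65. YAP/TAZ targets were lower for 15 of 22 and higher for 2 (16 and 2 adjusted over the list alone; adjusted p = 0.014 with an estimated correlation), including CCN1 (-1.42) and AMOTL2 (-1.30). These were the lists that held with an estimated correlation.

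Further lists passed with the preset correlation only. Ribosomal protein genes were higher for 49 of 74 (51 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), with RPL22 at 0.48. Hypoxia and glycolysis genes were higher for 24 and lower for 3 of 30 (25 and 3; adjusted p = 0.35), with LDHA at 0.65 but the glucose transporter gene SLC2A3 at -2.07. Proliferation genes were lower for 22 and higher for 2 of 36 (23 and 2; adjusted p = 0.26), CCNE2 by the most of those named (-0.89). MHC class I genes were lower for 11 of 17 (11; adjusted p = 0.26), including the immunoproteasome gene PSMB10 (-1.30) and the transactivator gene NLRC5 (-0.73). Cholesterol synthesis genes were lower for 15 and higher for 4 of 25 (16 and 4; adjusted p = 0.26), with INSIG1, which encodes a sterol sensor of the pathway, at -0.57 and the lanosterol synthase gene LSS at -0.54. Wnt/β-catenin targets were higher for 8 and lower for 4 of 18 (8 and 4; adjusted p = 0.26), led by RNF43, a ubiquitin ligase that removes Wnt receptors, at 29 against 4.63 CPM (2.65). Early NF-κB targets were lower for 13 and higher for 4 of 35 (13 and 4; adjusted p = 0.35), TNFAIP3 at -1.38 and KLF6 at -0.73. NF-κB and IκB components were lower for 12 and higher for 4 of 27 (13 and 4; adjusted p = 0.26). Heat shock, histone, retinoic acid and unfolded protein lists were lower for 10 of 20, 7 of 17, 10 of 17 and 12 of 27 members, and higher for 1, 0, 4 and 3 (adjusted p = 0.33, 0.26, 0.26 and 0.42 with an estimated correlation). With each library's GC trend removed, the early NF-κB targets, the NF-κB components and the unfolded protein list no longer passed camera (adjusted p = 0.057, 0.073 and 0.057).

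The measured genes of intestinal identity did not move one way in N108. Many stem cell and enterocyte markers, such as LGR5, OLFM4, VIL1 and FABP1, were not among the genes tested. The adult stem cell list had 7 higher and 6 lower of 18 members and did not pass camera, with EPHB2 at 0.66 and SOX9 at -0.68. In the fetal-like list 7 were higher and 14 lower of 27, with ANXA3 at -2.73 and KRT80 at -2.19, and camera did not call it. Absorptive enterocyte genes had 3 higher and 4 lower of 8: DPP4, a brush border peptidase gene, was at 91 CPM against 27.6 CPM (1.72), while CEACAM1 (-2.56) and MUC13 (-3.92) were lower. HOX genes had 8 higher and 11 lower of 32, Polycomb members 8 and 10 of 30, immediate early genes 14 and 13 of 35 with EGR1 at 1.82, and epithelial junction genes 4 and 10 of 24. Secretory lineage genes had 4 and 3 of 11, Notch genes 4 and 4 of 16, mesenchymal genes 6 and 7 of 15, p53 targets 5 and 11 of 29, NRF2 targets 9 and 4 of 22, and mitochondrially encoded transcripts 0 and 1 of 15. Among markers of cells that a cell line should not hold, 5 leukocyte genes were measured (1 higher, 1 lower), 8 fibroblast genes (2 higher, 4 lower) and 6 endothelial genes (1 higher, 2 lower), none of them lists that camera called. edgeR called 3972 genes higher and 4107 lower in N108, 1053 of them by at least 2-fold.

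M3 differed from WT by more genes. SPARCL1, a secreted matrix protein gene (chromosome 4, 87473335 to 87531061), stood at 30.2 CPM in M3 and 0.112 CPM in WT (log2 fold change 8.02, SE 0.14, adjusted p = 2.9e-26), while its relative SPARC (chromosome 5, 151661096 to 151687165) was at 0.41 CPM against 57.1 CPM (-7.12). RIMS1, a synaptic vesicle gene, was at 6.71 ± 0.47 CPM in M3 and at 0 counts in WT, which makes it at least 431-fold higher against a floor of 3 counts over the group. TIMP3, a metalloproteinase inhibitor gene, was at 1.91 against 0.0133 CPM. APOBEC3G, a cytidine deaminase that restricts retroviruses (chromosome 22, 39077005 to 39087743), was at 0.0742 CPM in M3 against 50.4 ± 2.1 in WT (-9.37, SE 0.14, adjusted p = 5.3e-28). PLEKHS1 was lower as well (-8.88), LRP2, which encodes the endocytic receptor megalin, was at 0.0173 against 8.78 CPM, and SEMG1, ZNF502 and the matrix gene TNC had 0 counts in untreated M3 and were at least 585-fold, 248-fold and 128-fold lower. ACSL5 was higher in M3 too, at 653 ± 6.2 CPM.

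Interferon-stimulated genes were lower in M3 for 25 of 28 and higher for 1 (25 and 1 adjusted over the list alone; adjusted p = 0.00012 with an estimated correlation), with IFI35 at -2.16, BST2 at -2.05 and IFIT1 at -1.99. YAP/TAZ targets were lower for 17 of 22 and higher for 2 (17 and 2; adjusted p = 0.013 with an estimated correlation), including the ecto-nucleotidase gene NT5E (-1.45) and the kinase gene LATS2 (-1.07). Another 16 lists passed with the preset correlation alone. Ribosomal protein genes were higher for 73 of 74 (73; adjusted p = 0.16 with an estimated correlation), with RPL22 at 0.87 and RPL9 at 0.86. Proliferation genes were lower for 30 of 36 (31; adjusted p = 0.12), such as the centromere histone gene CENPA (-0.93) and AURKA (-0.82). Cholesterol synthesis genes were lower for 20 and higher for 2 of 25 (20 and 2; adjusted p = 0.14), with INSIG1 at -1.35 and LSS at -0.96.

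Without LGR5, ASCL2 and OLFM4, which were not among the genes tested, the adult intestinal stem cell list was lower in M3 for 12 of 18 members. It was higher for 3 (12 and 3 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). ZNRF3 (-1.11), a negative regulator of Wnt signalling, and the transcription factor gene SOX9 (-0.77) were among the lower ones. Fetal-like genes were lower for 14 and higher for 8 of 27 (14 and 8; adjusted p = 0.32), ANXA3 (-3.22) and KRT80 (-3.20) most among those named. Enterocyte genes were lower for 5 and higher for 2 of 8 (5 and 2 adjusted over the list alone; adjusted p = 0.17), with CEACAM1, an adhesion molecule gene, at 1.29 CPM against 22.2 CPM (-4.11). Epithelial junction genes were lower for 11 and higher for 2 of 24 (11 and 2; adjusted p = 0.14), KRT18 at -0.99 and CDH1, the E-cadherin gene, at -0.56. HOX genes were lower for 13 and higher for 6 of 32 (13 and 7; adjusted p = 0.16), HOXB4 at -1.97 and HOXB6 at -1.66. Hypoxia genes went both ways, 20 higher and 5 lower of 30 (20 and 5; adjusted p = 0.54), with ADM at 0.94 and SLC2A3 at -3.73. Early NF-κB targets were lower for 16 and higher for 3 of 35 (adjusted p = 0.32), TNFAIP3 at -1.71 and PLAU at 0.99, and NF-κB components lower for 15 and higher for 2 of 27 (adjusted p = 0.14). Retinoic acid, MHC class I, heat shock, histone and unfolded protein lists were lower for 11 of 17, 10 of 17, 13 of 20, 8 of 17 and 13 of 27 members, and higher for 3, 2, 1, 0 and 4 (adjusted p = 0.16, 0.27, 0.27, 0.27 and 0.47 with an estimated correlation). The fetal-like, enterocyte, HOX and unfolded protein lists no longer passed camera with the GC trend removed (adjusted p = 0.07, 0.054, 0.055 and 0.13). edgeR called 4974 genes higher and 5105 lower, 1763 by at least 2-fold.

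**Figure D4:**
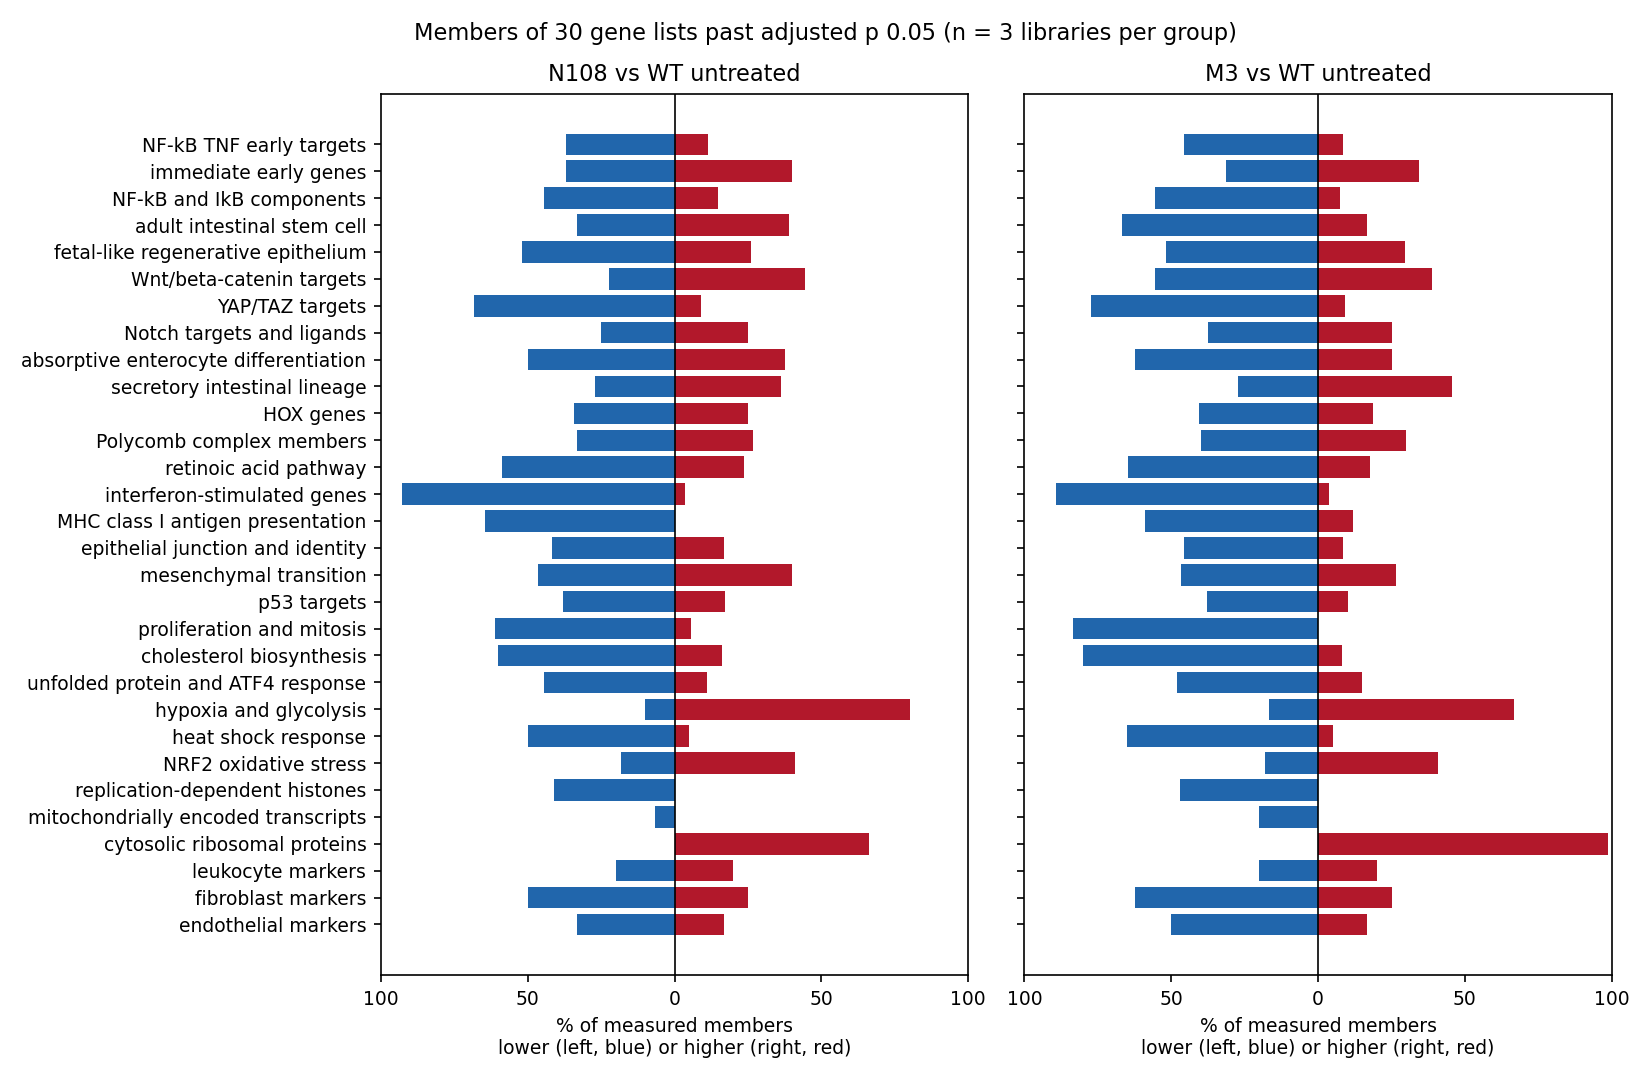
Percent of the measured members of 30 gene lists (vertical) that were lower (left, blue) or higher (right, red) than in untreated WT cells past an adjusted p of 0.05 (horizontal), for N108 and M3, with 3 libraries per group. Interferon-stimulated genes were lower for 26 of 28 members in N108 and 25 of 28 in M3, and ribosomal protein genes higher for 49 and 73 of 74.

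Both mutants shared many differences from WT. Untreated, 2946 genes were higher in both and 3157 lower in both, where independent lists would share 1040 and 1100, while 152 were higher in N108 and lower in M3 and 104 the reverse. Interferon-stimulated genes, YAP/TAZ targets and PLEKHS1 were lower in both, and ACSL5 higher. Because both comparisons used the same WT libraries, unchanged groups were simulated against those libraries. Over 12665 genes, the log2 fold changes of the mutants had a Pearson correlation of 0.817 and a covariance of 0.161, and 80.2% had the same sign, against 0.502, 0.00325 and 66.8% in the simulations. Their covariance above the simulated one was 0.158. Taken from separate WT libraries, with N108 untreated and M3 with TNF, the correlation was 0.768, the covariance 0.156 and the share of one sign 75.9%, and 2675 genes were higher and 2976 lower in both (1070 and 1140 for independent lists).

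N108 and M3 were also compared directly, untreated. SPARC was higher in N108 by 6.48 (SE 0.1), at 36.6 against 0.41 CPM, and APOBEC3G by 5.92 (SE 0.19). ZNF502 was at least 325-fold higher in N108 and RIMS1 at least 442-fold lower, each against 0 counts in the other line. Enterocyte genes were higher in N108 for 7 of 8 (7 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), with DPP4 at 1.87, CEACAM1 at 1.55 and HNF4A, a transcription factor gene of the gut epithelium, at 3.87 against 1.1 CPM (1.81). Adult stem cell genes were higher in N108 for 12 and lower for 2 of 18 (13 and 2; adjusted p = 0.068 with an estimated correlation), with RNF43 at 29 against 2.92 CPM (3.31, SE 0.078) and AXIN2 at 1.05. Wnt/β-catenin targets were higher for 11 and lower for 4 of 18 (12 and 4; adjusted p = 0.082), HOX genes for 14 and 2 of 32 (14 and 2; adjusted p = 0.068) and proliferation genes for 28 and 1 of 36 (29 and 1; adjusted p = 0.085). Cholesterol synthesis genes were higher for 17 and lower for 2 of 25 (18 and 2; adjusted p = 0.11), while ribosomal protein genes were lower for 73 of 74 (73; adjusted p = 0.11). NFKBIA was lower in N108 (-1.37). In total 3130 genes were higher and 2864 lower in N108, 679 by at least 2-fold.

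The mutants were also compared with WT in the presence of TNF. In N108, interferon-stimulated genes were lower for 25 of 28 (25 lower and 1 higher adjusted over the list alone; adjusted p = 5.4e-05 with an estimated correlation) and YAP/TAZ targets lower for 17 and higher for 2 of 22 (18 and 3; adjusted p = 0.012). Early NF-κB targets were lower for 18 and higher for 5 of 35 (19 and 5; adjusted p = 0.2), with the transcription factor genes IRF1 at -0.83 and KLF6 at -0.66, and ribosomal protein genes higher for 53 and lower for 1 of 74 (55 and 1; adjusted p = 0.4). PLEKHS1 was at -8.09. CXCL8 was lower than WT in N108 (112 against 132 CPM), a direction that turned to 0.01 (adjusted p = 0.94) with the GC trend of each library removed. In M3, interferon-stimulated genes were lower for 24 and higher for 1 of 28 (24 and 1; adjusted p = 0.00016), YAP/TAZ targets lower for 17 and higher for 3 of 22 (17 and 3; adjusted p = 0.02) and epithelial junction genes lower for 15 and higher for 2 of 24 (15 and 2; adjusted p = 0.04), each with an estimated correlation. The adult stem cell list was lower in M3 for 13 and higher for 2 of 18 (14 and 2; adjusted p = 0.09 with an estimated correlation). Early NF-κB targets were split, 12 higher and 12 lower of 35, and the list was not called (camera adjusted p = 0.94). In N108 4385 genes were higher and 4501 lower (1289 of them by at least 2-fold), and in M3 5120 and 5297 (2002 by at least 2-fold).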

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

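All tests of explanations in this part, the GC correction included, were chosen after the interactions had been seen. The difference in the response to TNF between each mutant and WT was tested for all genes, and 150 genes that the naming rule took from the largest changes, the lists that camera called and the NF-κB subunits were examined for it. For N108 the interaction passed for 498 genes in all and 20 of these 150, 15 with a higher and 5 with a lower response. The naming rule also took the extremes of the interactions themselves and the largest changes with TNF in WT. Counts out of the 150, for either mutant, are therefore partly set by the selection. TNFAIP3 (0.68), NFKBIZ (0.76), CXCL8 (0.67), CXCL1 (0.87) and JUN (0.42) rose by more in N108 on the log2 scale. Untreated, each had a lower mean than in WT, such as CXCL8 at 1.02 against 1.92 CPM. With TNF, TNFAIP3 was below WT (157 ± 15 against 255 ± 10 CPM). The means of CXCL8 (112 ± 6 against 132 ± 15 CPM) and JUN (142 ± 17 against 156 ± 11 CPM) were lower too. JUN's difference lay within the SDs, and CXCL8's did not remain with the GC trend of each library removed. Means of NFKBIZ (54.5 ± 4.5 against 53.8 ± 2.8 CPM) and CXCL1 (95.1 ± 14 against 92 ± 6.4 CPM) were above WT only within the SDs. In CPM, the larger rises of these 5 in N108 therefore lay in their lower untreated levels, not in a higher level with TNF. PLK3 (0.38) and GDF15 (0.57) were higher in response as well. ADAM8 (1.23), LINC02990 (1.27), SYT8 (1.20), IL11RA (1.03), CAPN3 (1.14), ATG9B (0.93), HOXB5 (0.34) and HOXB6 (0.26) had higher interaction estimates, and all 8 of them fell with TNF in WT. The response was lower for EGR3 (-0.76), DEPP1 (-0.56), ADRB1 (-0.72), SKIDA1 (-0.78) and ODAM (-0.72). BIRC3, named for a list that camera did not call and so outside the 150, was lower in response too (-0.67). With the GC correction TNFAIP3, NFKBIZ, EGR3, DEPP1, ADRB1, ADAM8 and LINC02990 stayed past the threshold, and the others of the 20 did not. JUN shrank from 0.42 to 0.31, whereas CXCL8 went from 0.67 to 0.95 and CXCL1 from 0.87 to 0.93, their calls ending because the SE grew (0.15 to 0.25 and 0.23 to 0.34). TNFAIP3, NFKBIZ, EGR3, DEPP1, ADAM8, LINC02990, SYT8 and ADRB1 kept their calls with any single library left out, and the others of these 20 lost theirs without at least 1 library, CXCL8 for example without N108 untreated replicate 1 (adjusted p = 0.056).

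For M3 the interaction passed for 60 genes and 14 of these 150, 11 higher and 3 lower. The higher ones were CXCL8 (1.63), TNFAIP3 (1.44), HAL (1.42), NFKBIZ (1.33), CXCL1 (1.13), ATG9B (1.05), JUN (0.74), NUAK2 (0.63), NFKBIA (0.58), ATF3 (0.57) and ZFP36 (0.35). ADRB1 (-0.91), DEPP1 (-0.75) and TSC22D3 (-0.51) were the lower ones. CXCL8, TNFAIP3, NFKBIZ, NFKBIA, JUN, ATF3 and DEPP1 kept their calls with any single library left out, and the others of these 14 did not, all of them losing the call without WT untreated replicate 1 (adjusted p from 0.051 for TSC22D3 to 0.11 for ATG9B). Among 82 splits that regrouped the libraries, 1 split, the real one, gave as many interactions for each mutant. The highest count of another split was 0 against the real 498 for N108 and 2 against the real 60 for M3, shares under 0.05. The other splits put TNF and untreated libraries together, which adds the TNF response to the spread and keeps their counts low, so these shares alone do not rule out differences between single libraries.

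A trend with GC content that differs between libraries is a candidate explanation for much of the N108 pattern: removing it left 115 of the 498 genes called in the same direction. The median absolute log2 interaction of the 498 went from 0.44 (quartiles 0.34 to 0.62) to 0.29 (0.18 to 0.49), so many calls ended because the estimate itself shrank. In M3 the same step left 59 of 60 genes, with a median of 0.69 before and 0.68 after, which argues against GC content as the source of that pattern. A lower level before TNF with the same level after it was examined as well. The 54 genes with a higher interaction estimate in M3 lay above WT with TNF as a set (median 0.44, quartiles 0.16 to 0.77) and at -0.15 untreated. That set also held genes that fell in WT, such as ATG9B (1.53 to 0.711 CPM in WT, 2.35 to 2.26 CPM in M3). A fall in WT can place such genes above WT with TNF, so these medians cannot decide the question for genes that TNF raised. TNFAIP3 (-1.71 untreated, -0.27 with TNF), NFKBIZ (-1.04, 0.29) and CXCL8 (-1.01, 0.62) were lower untreated, so a lower starting level stays open as part of their difference. A difference that comes with the mutation or with the clone stays open and untested, since 1 line stands for each genotype.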

How the results depend on the processing

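The GC correction and the list tests with a library left out were added after the data had been seen; the other settings were planned. DESeq2 size factors and the replicate block left all 20 counts of genes and lists within 1.5 times, the stricter filter all 10 counts of genes. Replicate numbers were shared across groups, but they did not pair the libraries: the deviations of 45 same-numbered pairs correlated between -0.15 and 0.10. With the replicate block the counts for the 10 comparisons were 892 and 200 (TNF in WT and N108), 248 (TNF in M3), 7980 and 9962 (N108 and M3 against WT untreated), 8747 and 10359 (with TNF), 5867 (N108 against M3), 372 and 49 (interactions of N108 and M3).

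A 2-fold threshold left 99, 50 and 64 genes for TNF in WT, N108 and M3, 1053 and 1763 for N108 and M3 against WT untreated, 1289 and 2002 with TNF, 679 for N108 against M3, and 28 and 9 interactions for N108 and M3; fewer genes pass by construction. With an estimated correlation 5, 3 and 6 lists passed for TNF in WT, N108 and M3, 2 and 2 for the mutants against WT untreated, 2 and 3 with TNF, 1 for N108 against M3 and 1 for the M3 interaction. For TNF in N108, DESeq2 gave 347 genes, no low-count filter 652, and only the groups compared 138. The N108 interaction had 1140 genes with DESeq2, 1362 with no filter and 147 with the GC correction, and its lists went from 0 to 5 with that correction. The M3 interaction had 156, 265 and 230 genes in the same settings, and the share of higher calls went from 90% to 79.6% with the GC correction. CXCL8 in N108 against WT with TNF turned from -0.23 to 0.01 with the GC correction. Except where the fold threshold sets it or the GC trend is removed, the cause was not tested.

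With each library left out in turn, counts ranged from 432 (without WT TNF replicate 3) to 1023 for TNF in WT, with 562 without WT untreated replicate 2. They ranged from 143 (without N108 untreated replicate 2) to 1333 (without N108 TNF replicate 3) for TNF in N108, with 151 without N108 TNF replicate 2, and from 189 to 214 for TNF in M3. Against WT they were 6873 to 7429 for N108 and 9141 to 9706 for M3 untreated, and 7737 to 8705 and 9466 to 9764 with TNF; N108 against M3 gave 4913 to 5353. The N108 interaction ranged from 183 (without WT TNF replicate 3) to 2430 (without N108 TNF replicate 3). It was 190, 249 and 318 without WT untreated replicate 2, WT untreated replicate 3 and WT TNF replicate 2, 227 and 199 without N108 untreated replicates 1 and 2, and 277 and 191 without N108 TNF replicates 1 and 2. The M3 interaction ranged from 14 (without WT untreated replicate 1) to 125 (without WT TNF replicate 1), with 16 and 29 without WT untreated replicate 2 and WT TNF replicate 3, 21 without M3 untreated replicate 2, and 24, 23 and 37 without M3 TNF replicates 1, 2 and 3. Lists called ranged over 10 to 13, 7 to 10 and 9 to 11 for TNF in WT, N108 and M3, 13 to 14 and 15 to 17 for N108 and M3 against WT untreated, 12 to 17 and 15 to 16 with TNF, 9 to 12 for N108 against M3, and 9 to 14 for the M3 interaction. For the N108 interaction they were 0 to 5, with 5 without WT TNF replicate 2 and 1 without WT untreated replicate 3, N108 untreated replicate 2 or N108 TNF replicate 1. Where a group kept 2 libraries, it was assumed to vary like the others. Depth limited genes near the floor of 3 counts per group.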

Other observations

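Splits of the samples, the tests around NFKBIA and those on differences shared by the mutants were all run after the results had been seen; the comparisons with WT were planned. Genes of the retinoic acid pathway, which controls gut homing and epithelial differentiation, were mostly lower in both mutants untreated, with 10 lower and 4 higher of 17 in N108 and 11 lower and 3 higher in M3. TGM2, which encodes transglutaminase 2 and responds to retinoic acid, was lower by a log2 fold change of -2.14 in N108 and -2.82 in M3. The list's adjusted p with an estimated correlation was 0.26 and 0.16. Genes of the MHC class I pathway, which presents antigen, were lower for 11 and 10 of 17 members, with the peptide-loading gene TAPBP at -0.46 in N108 (adjusted p = 0.26 in N108 and 0.27 in M3 with an estimated correlation). Between the mutants, N108 had higher mesenchymal genes for 6 and lower for 1 of 15 (adjusted p = 0.11 with an estimated correlation), and DKK1, a secreted Wnt antagonist gene, was higher in N108 by 1.43.

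NFKBIA was lower in N108 than in WT with and without TNF. Causes were tested in untreated cells only. A loss of the chromosome segment around it is argued against by the 38 expressed genes within 5 Mb, whose median log2 difference was 0.11 (quartiles -0.12 to 0.30, lowest -0.81). Loss of the transcript from 1 of 2 copies with no other change would give a value near -1, and the measured one was -1.60 with an SE of 0.053. Lower NF-κB target expression in general is argued against as the whole cause by the other 34 early targets, with a median of -0.06 (quartiles -0.42 to 0.11, lowest -1.38). Early targets still leaned lower: at an unadjusted p under 0.05, 15 of 35 were lower and 4 higher untreated, and 19 and 5 with TNF. The lower ones included NFKBIA itself in both conditions. Of all 19038 genes, 9344 passed that unadjusted p untreated and 9987 with TNF. Among all genes past the adjusted threshold, 4107 were lower and 3972 higher untreated, and 4501 and 4385 with TNF. A part from lower target expression, alone or together with loss of 1 copy, is therefore not excluded. The edit of the locus and a property of the clone remain as well and cannot be told apart, because the labels tell apart 1 N108 line. Either may account for the lower level.

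Differences from WT shared by N108 and M3 covered 2946 genes higher and 3157 lower in both. Chance values of the shared WT libraries are argued against as their whole cause by the covariance of the log2 fold changes, 0.156 with separate WT libraries against 0.00325 in simulated unchanged groups. Gain or loss of whole chromosomes is argued against by the medians per chromosome, whose largest absolute value over both mutants was 0.1. A property of the WT cells used, or of the cloning, may be shared in the same way as an effect of the mutations, and these cannot be told apart with 1 line per genotype.

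For the other 8 comparisons the libraries allow 10 splits of 3 against 3, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes. Every other split put libraries of both groups together, which adds their difference to the spread and keeps its count low. These counts alone therefore do not rule out differences between single libraries. The real counts and the highest of the other splits were 987 and 0 for TNF in WT, 228 and 2 for TNF in N108, 262 and 1 for TNF in M3, 8079 and 0 for N108 against WT untreated, and 10079 and 0 for M3 against WT untreated. They were 8886 and 0 for N108 and 10417 and 0 for M3 against WT with TNF, and 5994 and 0 for N108 against M3.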
